A study of Mus musculus with 45 samples.

How the data were processed

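Total RNA of mouse tissues was measured on Affymetrix GeneChip arrays of an older set (U74A, U74B and U74C) and a newer set (430A and 430B). The values are signal intensity per probe set, and the authors computed this intensity with MAS5/GCOS and scaled each array, per the labels and the series description. The version, masks and probe settings of that software are not stated. In the deposited tables every array had a mean of 499.5 to 499.9 between its 2nd and 98th percentile, which shows a scaling target of 500, and the values were linear and above 0. The tables hold no detection calls. The deposited scanner records were read only for chip type, scanner type and whether arrays were scanned on the same day. The median signal of an array ranged from 149.8 to 324.0, and the number of arrays limits the precision of every value.

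Each signal was divided by the median of its array, floored at 0.25 array medians and taken to log2. Between 19.6% and 24.3% of values lay under this floor, depending on the array type. Where a ratio had one array under the floor it is a bound, and its fold is written as at least that size. Gene symbols came from the platform annotation, updated by gene identifier to the GRCm38.p6 annotation, which also gave chromosomes. Probe sets assigned to several genes are named by their identifier, and probe sets without a gene are kept in the tests but not in gene counts.

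For each tissue, one array per genotype and array type was available, so no p-value was computed within a pair. A gene was compared in a pair when at least 1 of the 2 arrays reached its array median, and its value is that of the probe set with the highest mean signal. A size of at least 2-fold was the only criterion within a pair. Across tissues, the log2 ratio of each tissue was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, tissue as the pair), separately for each array type, with Benjamini-Hochberg adjustment over all probe sets of that array type whose mean over the arrays reached 1 array median. These p-values measure the spread of the same contrast between tissues, moderated by limma towards the spread of all probe sets. Where a test has 2 pairs, a probe set has 1 residual degree of freedom of its own. Prior degrees of freedom from the other probe sets were 9.62 on 430A, 18.6 on 430B and 48.43 on U74A in the distal test. The error in these tests therefore comes mostly from other probe sets. The labels do not give the number of animals behind an array, nor their sex.

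The tissues entered 3 tests. The maternal against the paternal proximal duplication was tested over carcass, heart, liver and placenta on the older set (heart was not run on U74C) and over brain and embryo on the newer set, and the maternal distal duplication against normal was tested over embryo and placenta on the older set. In simulated data with 200 changed probe sets, drawn 20 times from the fitted variances, 4 pairs recovered 29.4% of probe sets with a log2 size of 1, 92.9% with a size of 2 and 99.8% with a size of 4, and on average 5.2% of calls were false. With 2 pairs on 430A, 45.0% of probe sets with a size of 1 and 97.3% with a size of 2 were recovered, and the false share averaged 12.9% and reached 30.0% in one simulation. With 2 pairs on U74A, 41.9% with a size of 1 and 98.0% with a size of 2 were recovered, with an average false share of 7.4%. Each simulated change had the same size in every tissue, with noise drawn from the fitted model. These shares may not hold for genes whose ratio differs between tissues. Grb10 (93691_s_at), at -3.84 in carcass, -4.09 or lower in heart and -1.81 in placenta on the log2 scale, was not called. In liver both its arrays were under the floor, and the resulting ratio of 0 entered the test.

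There were 22 gene lists: imprinted genes in 6 lists by region and expressed parental copy (proximal and distal chromosome 7, proximal chromosome 11, other chromosomes), sex chromosome markers, and markers of erythroid cells, hepatocytes, the insulin and IGF axis, cardiac muscle, skeletal muscle, junctional zone trophoblast, labyrinth trophoblast, decidua, neurons, glia, proliferation, the immediate early and heat shock response, hypoxia, epidermis, and bone and cartilage. Within a pair, a list with at least 3 measured members was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size and similar mean signal. Across tissues, lists were tested with camera (preset correlation 0.01, and estimated correlation) and fry from limma. fry asks whether the genes of a list move one way on balance, and does not compare them with other genes.

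The genes named are every measured imprinted gene of chromosomes 7 and 11 that bears on a comparison; in each pair the 5 highest and 5 lowest ratios among 2-fold genes with at least 2 array medians in 1 of the 2 arrays; up to 20 probe sets per test past an adjusted p of 0.05; the 15 genes with the largest smallest ratio among those 2-fold in the same direction in every tissue; and up to 4 members of other lists with the largest median ratio. Genes named outside this rule are marked where they occur. The tests, the lists, this rule and the other settings tried were chosen before the data were examined, except where stated. These settings were scaling by the 75th percentile, quantile normalization, no further scaling, floors of 0.5 and 0.05 array medians, no filter or a filter at 2 array medians, eBayes without trend, unpaired tissues, each tissue left out in turn, the median of all probe sets of a gene, and a 3-fold size. An exclusion of chromosome X and Y genes, an exclusion of marker lists of other tissues and an 8-fold size were added after the data had been seen. A Fisher test of 2-fold genes on chromosomes 7 and 11 had been planned for each pair. It was replaced by shares with Wilson 95% intervals, because genes of one pair of arrays are not replicates, and this was decided after its p-values had been seen. The intervals treat genes as independent draws and cover no variation between animals. Further tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.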

Results

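Gene expression was compared in 45 arrays from 6 tissues of mice with T65H, a reciprocal translocation between chromosomes 7 and 11 with breakpoints in bands 7F4 and 11B1.1. Crosses between carriers give animals in which both copies of a chromosome segment come from the same parent, called a uniparental duplication. Maternal duplication of proximal chromosome 7 comes with paternal duplication of proximal chromosome 11 and was measured on 15 arrays. The reciprocal paternal duplication of proximal chromosome 7 was also measured on 15 arrays, maternal duplication of distal chromosome 7 on 6 arrays, and T65H mice without a uniparental duplication, called normal, on 9 arrays. Brain gave 4 arrays, carcass 6, embryo 10, heart 4, liver 9 and placenta 12. Embryo and placenta were taken at 13.5 days post coitum, and the other tissues were from newborns. Every combination of tissue, genotype and array type was hybridised to 1 array, so ratios within a tissue have no replicate error. Signals are given in multiples of the array median.

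The proximal comparison asked which transcripts depend on whether proximal chromosome 7 came from the mother or the father. Proximal chromosome 11 had the opposite origin, so effects of these segments on genes elsewhere cannot be told apart. Peg3, a zinc finger gene expressed from the paternal copy, was almost lost in the maternal duplication in all 6 tissues on its brightest probe set. In brain its signal was 0.253 in the maternal and 23.9 in the paternal duplication, and in embryo 0.278 and 44.2. Over brain and embryo, Peg3 fell by 6.94 on the log2 scale (probe set 1433924_at, SE 0.26, limma adjusted p = 9.27e-08, lower in 2 of 2 pairs). Over carcass, heart, liver and placenta it fell by 7.25 (96765_at, SE 0.27, limma adjusted p = 5.59e-06, lower in 4 of 4 pairs) and its mean log2 ratio on a second probe set was -6.94 (101451_at, SE 0.30, limma adjusted p = 1.01e-05, lower in 4 of 4 pairs). The dimmer probe set 161316_f_at showed a smaller loss, with 1.02 in the maternal and 5.94 in the paternal liver.

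Ndn, which encodes the growth suppressor necdin, also fell over brain and embryo, on 5 probe sets with mean log2 ratios between -8.03 and -7.19. For 1455792_x_at the mean was -8.03 (SE 0.26, limma adjusted p = 4.49e-08, lower in 2 of 2 pairs). On the U74A array Ndn was 32.6-fold lower in carcass, at least 32.0-fold lower in heart and 3.17-fold lower in placenta (94811_s_at), while in newborn liver 94811_s_at was under the floor in both genotypes. A second probe set, 101059_at, was at least 4.82-fold lower in liver, with 0.235 against 1.21, and 5.85-fold lower in placenta. Peg3 and Ndn belong to the list of paternally expressed genes of proximal chromosome 7, whose medians were -3.96 in brain, -3.12 in carcass, -2.98 in embryo and -2.81 in placenta, each below all random lists. In liver the median of the list was -0.53, at percentile 14.4, with Peg3 the 1 of 3 members that was 2-fold lower. On 430A, 9 of the 11 probe sets of the list fell, and 11 did when adjusted over the list alone. On U74A, 2 of 5 fell, and 5 did when adjusted over the list alone. The list stood below other genes with camera on 430A (limma adjusted p = 5.48e-63) and U74A (limma adjusted p = 3.18e-27). With an estimated correlation the adjusted p was 0.712 on 430A and 0.0426 on U74A, and by fry from limma it was 0.335 and 0.00507.

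Other transcripts of the same region moved with Ndn. Magel2, a MAGE family gene next to Ndn, fell by 2.28 over brain and embryo (SE 0.28, limma adjusted p = 0.00653, lower in 2 of 2 pairs) and was at least 6.99-fold lower in placenta. Snhg14, a long noncoding host transcript of small nucleolar RNAs, fell by 5.72 over brain and embryo (1436964_at, SE 0.46, limma adjusted p = 9.42e-07, lower in 2 of 2 pairs). Its log2 ratios in liver and placenta were -1.88 and -1.87. A second Snhg14 probe set, 1455087_at, fell by 4.05 (limma adjusted p = 0.014, lower in 2 of 2 pairs), but its adjusted p ranged from 0.0522 to 1.0 under the 5 alternatives that ended the call. The platform annotation assigns further probe sets to Snurf and Snrpn together, whose transcripts overlap, and 4 of them lay on 430A. Of these, 1435716_x_at had a mean log2 ratio of -6.85, 1421063_s_at one of -5.86, 1415896_x_at one of -5.42 and 1415895_at one of -2.84 in the same test, with limma adjusted p up to 0.000119. On the other arrays, 1441905_x_at was at least 29.2-fold lower in brain, while 170824_i_at had a log2 ratio of 0.66 in carcass, the other way. Inpp5f, an inositol phosphatase gene, fell by 3.46 (1447757_x_at, SE 0.40, limma adjusted p = 0.000269, lower in 2 of 2 pairs). A second Inpp5f probe set, 1433542_at, fell by 3.20 (limma adjusted p = 0.00687), a call lost without a filter (0.249), without trend (0.0518) and without pairs (1.0). On U74C another Inpp5f probe set, 137065_at, had log2 ratios of -0.82 in carcass, -0.08 in liver and 1.18 in placenta, and in brain the dim 1442100_at was at 0.62, with 1.25 against 0.813. Mkrn3, a ring finger gene, was at least 15.5-fold lower in brain, with 0.016 in the maternal and 3.88 in the paternal duplication, and Usp29, a ubiquitin protease gene beside Peg3, was at least 17.1-fold lower there. Peg12 was 11.2-fold lower in placenta and 2.32-fold lower in carcass. Ipw, also of this list, had 1.25 and 1.23 in brain. Zfp264 gave no value.

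**Figure D1:**
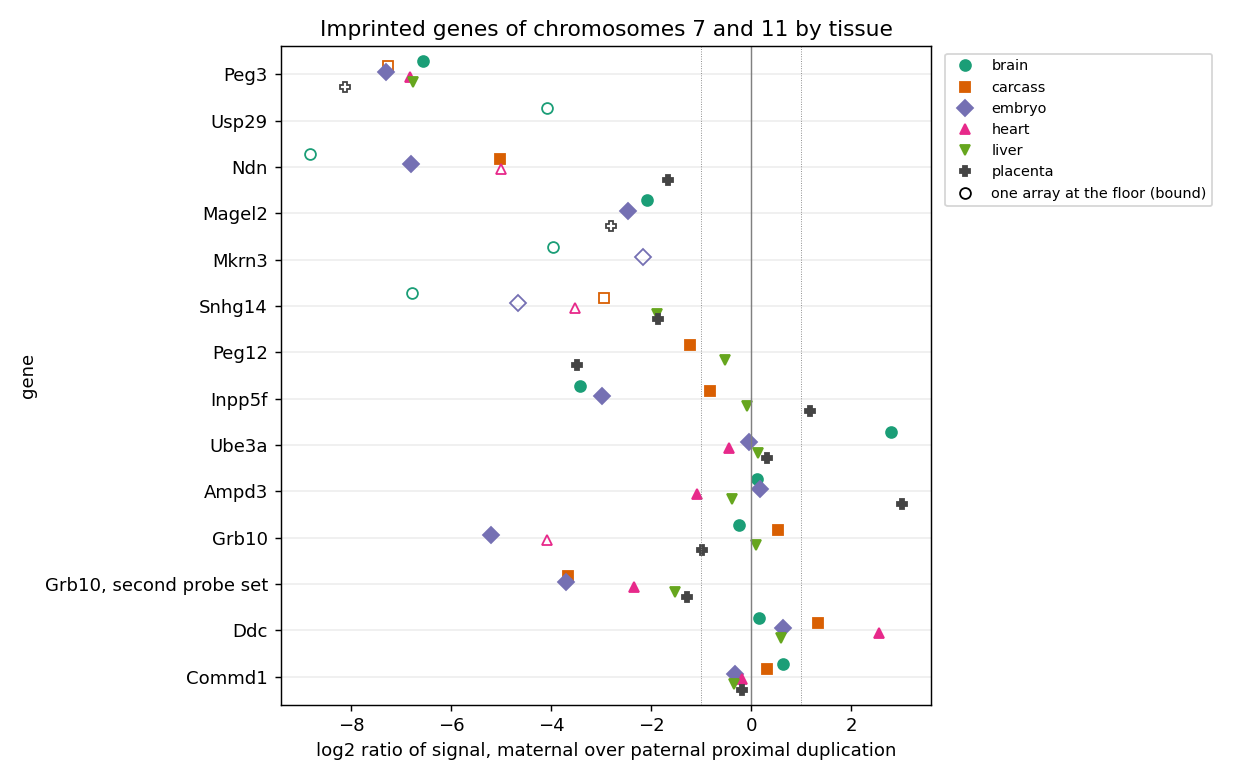
Log2 ratio of signal (x axis, maternal over paternal proximal duplication) of imprinted genes (y axis), with 1 point per tissue, open points for bounds where 1 array was under the floor, dotted lines at 2-fold, and Grb10 for its brightest and for a second probe set (93690_at, and 1425457_a_at in embryo). Peg3 lies between -8.12 and -6.56 in the 6 tissues, and Ube3a is at 2.79 in brain and -0.05 in embryo.

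Maternally expressed genes of proximal chromosome 7 differed between tissues in single pairs. Ube3a, the ubiquitin ligase gene lost in Angelman syndrome, had a signal of 8.50 in the maternal and 1.23 in the paternal brain (1416680_at), a log2 ratio of 2.79, and 8.01 and 8.29 in the embryo. In brain 2 dimmer Ube3a probe sets were at -0.48 (1431224_at) and -0.25 (1445727_at). Below the array median, 1416681_at was at 1.02 or higher, 1416682_at at 1.09 or higher and 1425206_a_at at 0.54. With the median of all Ube3a probe sets the brain value was 0.78. Ampd3, an AMP deaminase gene, was 8.08-fold higher in the maternal placenta, with 6.88 and 0.851, but had log2 ratios of -1.07 in heart and 0.11 in brain. Zim3 was 0.76 in brain and Zim2 0.80 in embryo on the log2 scale. The list had a median of 0.76 in brain, at percentile 94.7, and 0.18 in embryo, at percentile 73.7. No probe set of Atp10a or Zim1 reached the array median in these pairs.

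On proximal chromosome 11 the copies came from the opposite parent. Grb10, a growth factor receptor adaptor expressed from the maternal copy in most tissues, was 36.7-fold lower in the embryo with the maternal chromosome 7 duplication, with 1.91 against 70.1, while in brain the values were 5.35 and 6.34. Probe set 93690_at was 12.8-fold lower in carcass, 5.08-fold in heart, 2.87-fold in liver and 2.43-fold in placenta. The brightest Grb10 probe set on the older arrays, 170503_r_at, had log2 ratios of 0.54 in carcass and 0.10 in liver, where it did not follow, and -0.99 in placenta. Ddc, which encodes dopa decarboxylase, was 5.87-fold higher in heart, with 30.1 against 5.13, and its log2 ratios were 1.35 in carcass on 160074_at and -1.23 on 171186_at. Commd1 had a log2 ratio of 0.63 on 1424122_s_at and -1.61 on 1424121_at in brain. The chromosome 11 list had a median of -1.15 over carcass, heart, liver and placenta on U74A (camera, limma adjusted p = 0.0141), with an adjusted p of 0.459 under an estimated correlation. None of its 4 probe sets passed over all probe sets, and 2 did when adjusted over the list alone. Over brain and embryo on 430A the median of the list was -0.615 (camera, limma adjusted p = 0.61). Zrsr1 gave no value.

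Across the older arrays the 2 Peg3 probe sets were the only calls among 19779 tested, while 949 had an unadjusted limma p under 0.05 where 989 were expected by chance. Over brain and embryo 20 of 23266 probe sets passed, 1 higher and 19 lower, with 1015 at an unadjusted p under 0.05 and 1163 expected. The unnamed probe set 1449354_at rose by 2.78 (limma adjusted p = 0.00137, higher in 2 of 2 pairs), and the unnamed 1440557_at and 1445988_at fell by 3.16 and 2.54 (limma adjusted p = 0.0423 for each, lower in 2 of 2 pairs). These 2 falls lost their call under 5 and 6 alternatives, among them quantile normalization (limma adjusted p = 0.389 and 0.243). The log2 ratios of 1440557_at also lay far apart, at -4.73 in brain and -1.59 in embryo. Without further scaling 42 probe sets passed, 15 higher and 27 lower, and a filter at 2 array medians gave 7 higher and 18 lower. With tissues unpaired 0 passed (88 at an unadjusted p under 0.05). Leaving out liver or placenta on the older set gave 4 calls each in place of 2.

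In brain 771 of 12071 genes were at least 2-fold higher and 365 lower in the maternal duplication. Besides Ndn, Snhg14, Peg3, Usp29 and Mkrn3 at the low end, the high end held Xist, the noncoding RNA of X inactivation, which was 22.5-fold higher, Atg4a (15.6-fold), the class I histocompatibility gene H2-D1 (12.6-fold), Zfp593 (12.6-fold) and Fam241a (10.6-fold). Eif2s3y, a gene of the Y chromosome, was at least 7.82-fold lower on its brain probe set, at 0.006 against 1.95. Neuron markers had a median of -0.05, with the neurofilament gene Nefl at 1.22 and Camk2a at 1.47, and glia markers a median of 0.14. Erythroid markers had a median of 0.86, at percentile 99.5, with the haem synthesis gene Alas2 3.99-fold higher. Hypoxia genes had a median of -0.33, at percentile 0.87.

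In carcass 945 of 11586 genes were at least 2-fold higher and 664 lower. The highest ratios belonged to the lung surfactant genes Sftpc, with 59.9 against 0.684 or 87.6-fold, and Sftpb (20.6-fold), the airway secretory gene Scgb1a1 (42.5-fold), the cornified envelope gene Lce1l (47.7-fold) and the kallikrein Klk5 (21.7-fold). Epidermis markers were 2-fold higher in 7 of 8 members, with a median of 2.12 above all random lists, including filaggrin (Flg, 2.82), the keratin gene Krt14 (2.24 or higher) and Ivl (1.94). Bone and cartilage markers had a median of 1.37, with Matn1 at 2.61 or higher, Comp at 2.15 and Ibsp at 1.49. Cardiac muscle markers were 2-fold higher in 6 of 10 members, with Tnnt2 at 1.24 and Tnni1 at 1.21, while skeletal muscle had a median of 0.09. Genes of the insulin and IGF axis had a median of -0.53, below all random lists, with none 2-fold lower. At the low end with Peg3 and Ndn were Pdxdc1 (at least 23.3-fold), the urinary protein gene Mup5 (14.7-fold) and Slco6b1 (11.9-fold).

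In the embryo 283 of 12344 genes were at least 2-fold higher and 246 lower. The placental pregnancy-specific glycoprotein gene Psg21 was 27.5-fold higher, and the trophoblast genes Prl8a9 and Tpbpa were at least 18.1-fold and at least 16.6-fold higher, followed by 4933439C10Rik (at least 10.7-fold) and Ceacam13 (8.76-fold). Junctional zone trophoblast markers were 2-fold higher in 8 of 12 members, with a median of 2.15, while labyrinth trophoblast had a median of 0.05 and decidua one of 0.16. Hepatocyte markers were 2-fold higher in 7 of 11 members (median 1.32), among them Ahsg (1.98) and Apoa1 (1.32), and bone and cartilage in 5 of 8 (median 1.20). Epidermis stood at 0.74, erythroid markers at 0.50, hypoxia at 0.36 and neurons at -0.35. Tssk4 was at least 11.0-fold lower. Over brain and embryo, camera called the hepatocyte, erythroid, bone, junctional zone, skeletal muscle and cardiac muscle lists higher, with limma adjusted p up to 0.0491, and each had an adjusted p of 0.749 with an estimated correlation.

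In heart 522 of 9257 genes were at least 2-fold higher and 462 lower. Albumin (Alb) was 39.3-fold higher in the maternal duplication, with 28.7 against 0.729, and the liver genes Apoa1, Afp and Fga were 18.5-fold, 16.4-fold and 8.99-fold higher, with Kbtbd4 at 9.59-fold. Hepatocyte markers were 2-fold higher in 7 of 12 members, with a median of 1.10 above all random lists. Proliferation genes had a median of 0.68, at percentile 99.99, with the cyclin-dependent kinase Cdk1 at 1.70 and Rrm2 at 1.44. Cardiac muscle stood at -0.06. Immediate early and heat shock genes had a median of 0.04, with Egr2 at -2.57 or lower. Low-end genes other than Peg3 and Ndn were Pdxdc1 (at least 25.9-fold), Grb10 (93691_s_at, at least 17.0-fold) and Snhg14 (at least 11.5-fold).

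In placenta 1086 of 11247 genes were at least 2-fold higher and 780 lower. Gm9519 was at least 69.9-fold higher, Pdxdc1 26.9-fold, the apoptosis gene Xaf1 17.9-fold, Ahnak2 14.7-fold and the calcium channel gene Itpr3 11.4-fold. Decidua markers had a median of 1.13, at percentile 99.98, with Hoxa11 at 1.57 and Cryab at 1.38. Hepatocyte markers were 2-fold lower in 8 of 15 members, with a median of -1.04 and Apoa1 at -1.24. Junctional zone trophoblast had a median of -0.03, with 5 of 17 members 2-fold lower and 0 higher, and labyrinth trophoblast one of -0.23, and Prl5a1 was at -3.30 or lower. The lowest genes with Peg3 and Peg12 were Pdzph1 (at least 14.8-fold), 3110045C21Rik (11.2-fold) and Slc9a4 (at least 10.8-fold).

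Genes that differed 2-fold in the same direction in every tissue measured, with at least 3 tissues, numbered 19 of 11984. Of these 7 were higher and 12 lower, and the 31 other assignments of signs to the tissues gave up to 17, with a median of 13. Peg3 and Snhg14 were lower in 6 tissues and Ndn in 5. Lower in 3 tissues were Cage1 (median log2 ratio -2.19), Magel2 (-2.47), Tle6 (-1.72), Smlr1 (-1.56), 4930570G19Rik (-1.48), Gm20319 (-1.45), Gpa33 (-1.37) and Gm13490 (-1.57). Higher in 3 tissues were the dehydrogenase gene Sdr9c7 (2.10), Sgsm3 (1.82), 1810063I02Rik (1.74) and the neuropeptide precursor gene Vgf (1.61). For Snhg14, Ndn, Magel2 and other genes with an array under the floor the ratios are bounds.

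Genes on chromosomes 7 and 11 made up 16.9% of the 2-fold genes in brain (Wilson 95% interval 14.8% to 19.2%), 17.4% in carcass, 18.8% in embryo, 18.5% in heart, 17.3% in liver and 15.5% in placenta, against 15.7% to 16.1% of all genes compared. Whole chromosomes were counted, although only their parts proximal to the breakpoints were uniparental in the duplications. A share near that of all genes therefore does not describe the duplicated segments alone. At 8-fold, a size chosen after the counts had been seen, the share was 66.7% in embryo (8 of 12 genes, interval 39.1% to 86.2%) and 39.3% in brain (11 of 28 genes, interval 23.6% to 57.6%), with Peg3, Ndn and Snhg14 among them in both. The embryo genes also held Grb10, which was lower, and Psg21, Ceacam11, Ceacam13 and 4933439C10Rik, which were higher. Psg21 is a placental gene, and placental tissue in that embryo sample may be its source. The source of the higher Ceacam11, Ceacam13 and 4933439C10Rik was not tested. The embryo share can therefore not be read as an effect of the duplication alone. At 8-fold the share was 15.9% in carcass (7 of 44 genes), 15.8% in liver (15 of 95 genes), 23.8% in heart and 26.9% in placenta. Median scaling left a shift of more than 0.1 in the median log2 ratio of some arrays, 0.19 on 430B in brain, 0.13 on U74A in heart, 0.11 on U74A and -0.26 on U74C in liver, -0.12 on U74A and 0.24 on U74C for paternal against normal liver, 0.19 on U74B in placenta and, in the distal comparison, 0.15 on U74B in embryo. In brain the 100 probe sets shared by 430A and 430B had a median log2 ratio of -0.07 on 430A and 0.46 on 430B, so that brain ratios near 2-fold on 430B carry a shift of this size, and the difference had an SD of 0.34.

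Liver was the 1 tissue with all 3 genotypes of the proximal comparison. Peg3 had signals of 0.206 in the maternal duplication, 33.4 in normal and 30.6 in the paternal duplication (101451_at), and 0.543, 31.3 and 59.1 on 96765_at. Igfbp2, which encodes an IGF binding protein, had 5.59, 159 and 138. Psca had 6.83, 0.289 and 0.357, and the scavenger receptor gene Scara5 had 7.56, 0.304 and 0.296. Against normal, the maternal duplication had 1034 of 11293 genes at least 2-fold higher and 966 lower, the highest being Porcn (30.2-fold), Scara5 (24.9-fold), Psca (23.7-fold), Fyb2 (18.1-fold) and the transporter gene Slco4c1 (16.9-fold). The lowest were Peg3 (57.6-fold), Igfbp2 (28.5-fold), Dnaic1 (at least 26.0-fold), Apol7a (22.6-fold) and Plekhh3 (13.5-fold).

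The paternal duplication against normal had 1378 of 11335 genes at least 2-fold higher and 1210 lower. The highest were Xaf1 (18.9-fold), Mgarp (at least 18.5-fold), Fyb2 (15.8-fold), Cep57 (a log2 ratio of at least 3.91) and Pdxdc1 (14.4-fold). Lowest were Xist (at least 38.5-fold), Zfp574 (at least 16.6-fold), the mitochondrial carrier gene Slc25a10 (13.0-fold), Lin28a (11.7-fold) and G0s2 (11.6-fold). Maternal against paternal liver had 1285 of 11324 genes at least 2-fold higher and 1361 lower, with Xist at least 51.6-fold, Scara5 25.6-fold, 1810007D17Rik 20.1-fold, Psca 19.1-fold and Pcdh1 at least 13.1-fold higher. After Peg3 the lowest were Apol7a (44.9-fold), Csl (27.3-fold), Pdxdc1 (at least 26.3-fold) and Cnmd (26.2-fold). The erythroid list had medians of 0.71 for maternal against paternal, -0.70 for paternal against normal and -0.26 for maternal against normal, and the proliferation list had -0.45 for maternal against normal, at percentile 0.42. The paternal liver arrays were scanned on another day and another scanner type than the other liver arrays, in 3 of 3 array types, so that genotype and scan batch cannot be told apart in the comparisons with paternal liver, whereas maternal and normal liver shared day and scanner.

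The distal comparison asked which transcripts differ between maternal duplication of chromosome 7 beyond the breakpoint and normal. The translocation is reciprocal, so in animals with a balanced set of segments both copies of distal chromosome 11 came from the father. Effects of distal chromosome 11 were not told apart from those of chromosome 7. Igf2, the fetal growth factor gene expressed from the paternal copy, fell by 4.37 over embryo and placenta (98623_g_at, SE 0.24, limma adjusted p = 6.51e-20, lower in 2 of 2 pairs). Its signal was 11.2 in the embryo with the duplication and 241 in the normal embryo, and 9.97 and 197 in placenta. In the 6 proximal pairs the log2 ratio of Igf2 lay between -0.12 and 0.88, and Peg3 (96765_at) and Ndn (94811_s_at) in the distal pairs lay between -0.23 and 0.39. Dimmer Peg3 probe sets had 0.62 in embryo and -0.56 in placenta (101451_at) and -0.58 and -0.77 (161316_f_at).

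Maternally expressed genes of the distal cluster were higher in some cases and lower in others. Their list had a median of 0.41 in placenta, at percentile 99.9, and of 0.13 in embryo, at percentile 57.3. On U74A, camera gave an adjusted p of 0.0659 with limma, and none of its 9 probe sets passed, nor did any when adjusted over the list alone. On U74C its 3 probe sets had a median of -0.08 and a mean of -0.53 (camera, limma adjusted p = 0.138), with 1 lower when adjusted over the list alone. Cdkn1c, a cyclin-dependent kinase inhibitor gene, had 182 against 136 in embryo and 173 against 147 in placenta. The decoy receptor gene Tnfrsf23 had log2 ratios of 1.69 and 0.96, Nap1l4 0.70 and 1.08, Osbpl5 0.24 and 0.47, Tssc4 -0.22 and 1.07, Cd81 -0.18 and 0.41, Slc22a18 0.13 and -0.08 and Dhcr7 -0.35 and 0.19, each in embryo and placenta. Phlda2, a placental growth regulator, had 0.42 in placenta, and the trophoblast transcription factor gene Ascl2 had 68.6 against 98.2 there. Th was 0.25 and Tspan32 -1.06 in embryo, and Tnfrsf22 was -1.18 in placenta. Probe set 93028_at, which the platform annotation assigns to the overlapping pair H19 and Mir675, had 276 against 252 in embryo and 264 against 250 in placenta.

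**Figure D2:**
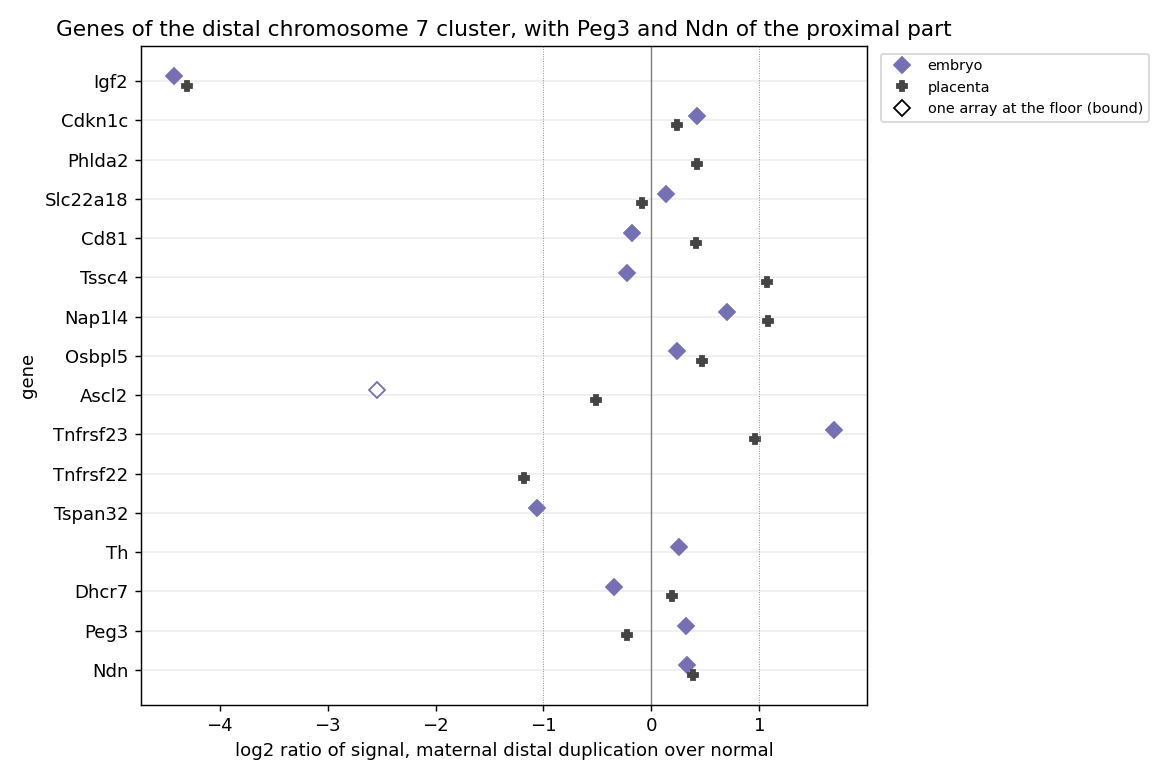
Log2 ratio of signal (x axis, maternal distal duplication over normal) of genes of the distal cluster and of Peg3 and Ndn (y axis), with 1 point for embryo and 1 for placenta, the open point being a bound; dotted lines mark 2-fold. Igf2 lies at -4.42 in embryo and -4.31 in placenta, and Cdkn1c at 0.42 and 0.24.

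Besides Igf2, 5 of 19251 probe sets passed in the distal test, with 641 at an unadjusted limma p under 0.05 and 963 expected. Probe set 101771_r_at, which is listed for several protocadherin alpha genes, rose by 2.13 (limma adjusted p = 6.05e-06, higher in 2 of 2 pairs). Gzmd, a granzyme gene of natural killer cells, rose by 1.33, and the catalase gene Cat and the RNase P gene Rpp14 fell by 2.01 and 1.71 (limma adjusted p = 0.0389 for each). Pdxdc1 rose by 3.15 (SE 0.45, limma adjusted p = 1.68e-05), but its ratios of 0.80 in embryo and 5.49 in placenta lay far apart. The SD of these ratios was 3.31, so that the SE rests mostly on other probe sets. Gzmd, Cat, Rpp14 and Pdxdc1 each lost the call under 4 alternatives, with limma adjusted p from 0.0562 to 1.0. The number of calls was 2 without trend, 3 without a filter, 12 and 13 under other scalings and 0 with tissues unpaired (47 at an unadjusted p under 0.05), and Igf2 passed in all of these except the last.

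In the distal embryo 1041 of 11364 genes were at least 2-fold higher and 899 lower. Xist was at least 27.2-fold, Syce3 15.5-fold, Glrx2 at least 12.3-fold, Cir1 at least 11.5-fold and the potassium channel gene Kcnma1 11.3-fold higher. With Igf2 at the low end were Tmem232 (at least 21.9-fold), Gip (18.6-fold), Traf2 (at least 16.9-fold) and the fibrinogen gene Fga (16.2-fold). Erythroid markers had a median of -0.83, below all random lists, with the haemoglobin gene Hbb-b2 at -1.18, and hepatocyte markers one of -0.76, with Ahsg at -1.14. Skeletal muscle stood at -0.30, with 3 of 13 members 2-fold lower, Tnni2 at -2.47 and Mylpf at -1.58 among them, and Chrna1 higher at 1.08, and neuron markers at 0.56, at percentile 98.8, with Syt1 at 1.35.

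In the distal placenta 593 of 11077 genes were at least 2-fold higher and 557 lower. The highest were Pdxdc1 (at least 44.8-fold), Gm9519 (17.1-fold), Gip (15.5-fold), the serine protease gene Tmprss4 (13.7-fold) and Klk1b21 (at least 11.7-fold). Next to Igf2 at the low end were Ppil6 (24.8-fold), Xist (16.9-fold), Adamdec1 (at least 14.6-fold) and the replication protein gene Rpa2 (at least 12.9-fold). Proliferation genes had a median of -0.50, at percentile 0.02, with Mki67 at -1.23 and Aurka at -0.89. Over embryo and placenta the proliferation list was lower by camera (median -0.33, limma adjusted p = 3.56e-05), with an adjusted p of 0.809 under an estimated correlation, and so was the erythroid list (median -0.16, limma adjusted p = 0.0428, and 0.809), although its median was -0.83 in embryo and 0.42 in placenta. On U74B the neuron list was higher by camera (median 0.78, limma adjusted p = 0.0113, and 0.701 with an estimated correlation). Junctional zone trophoblast had a median of 0.20 in placenta, labyrinth 0.02, decidua 0.29 and imprinted genes of other chromosomes -0.19.

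In the distal comparison 129 of 9864 genes were 2-fold in the same direction in embryo and placenta, 66 higher and 63 lower, while 196 were 2-fold in opposite directions. After Igf2, the lower genes with the largest smallest ratio were Gm7788 (median -2.61), the fibroblast growth factor gene Fgf10 (-2.48), the dUTPase gene Dut (-2.89), Gm36534 (-2.32) and Gm10039 (-2.32). The higher ones were Paqr5 (2.65), Armc12 (2.61), Zfp940 (2.57), the germ cell helicase gene Ddx4 (2.19), Dnm3 (2.71), Gm19705 (2.33), Lpcat2b (2.34), 1700041B01Rik (2.44) and 4933407L21Rik (2.39). With an array under the floor, as for Gm7788, Fgf10 and Dut, these medians are bounds. Genes on chromosomes 7 and 11 were 16.6% of the 2-fold genes in embryo and 18.4% in placenta (Wilson 95% interval 16.3% to 20.8%), against 15.8% and 15.9% of all genes compared. Here too whole chromosomes were counted, not only the parts beyond the breakpoints.

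The sexes of the animals are not given, and sex chromosome transcripts differed within pairs. Xist was 2-fold different in 8 of 10 pairs. In 7 of these, each gene out of the Y-linked Eif2s3y and Kdm5d that reached the array median went at least 2-fold the other way (in brain only Eif2s3y reached the array median), with Eif2s3y at -2.78 or lower in carcass, -3.43 or lower in heart and -3.16 or lower in liver, against Xist at 3.46, 3.09 and at least 5.69. Without genes of chromosomes X and Y, an exclusion chosen after this had been seen, the tests gave 2, 20 and 9 calls on the older proximal, newer proximal and distal sets, and all calls named above were among them. This exclusion leaves the ratios of other genes unchanged, so it cannot show whether sex affects them. In brain, carcass, heart and liver alike, Xist was higher and Eif2s3y lower in the maternal proximal duplication. Genotype and apparent sex cannot be told apart in those pairs.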

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

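Of the tests in this part, those of sex, of a scaling shift in heart and embryo and of other splits of the arrays were chosen after the result was seen. Albumin (Alb), Apoa1, Afp and Fga, genes of the liver, stood 39.3-fold, 18.5-fold, 16.4-fold and 8.99-fold higher in the heart of the maternal proximal duplication than in the paternal one. The median of the hepatocyte list, 1.10, lay 0.65 above the upper bound of random lists of equal brightness in that pair. That list holds the flagged genes and its position had been seen, so this is no separate test of a scaling shift. The median log2 ratio of the heart arrays was 0.13 on U74A and 0.05 on U74B, too small for the ratios of these genes. Liver RNA in that heart sample may be the source. Outside the list, 164 probe sets bright on the liver arrays and rare in heart had a median of 0.16, with 45 at least 2-fold higher and 8 lower. Rare was judged on the paternal heart signal, the denominator of these ratios, and this choice can raise the median. A paternal signal near the floor also leaves no room for a 2-fold fall. The 45 against 8 therefore cannot decide whether liver RNA was present. Taken next were 29 probe sets with at least 100 array medians in maternal liver and under 1 in paternal heart. They would need a median of 0.478% of liver RNA, and the choice of a low paternal heart signal can raise this value. Alb would need 5.48%, Kng1 3.56% and Apoa1 4.51% on 1 probe set but 1.09% on another, so the source of their excess stays open. Cdk1 and Rrm2, which were higher in the same heart, are not liver markers, and a biological difference between the genotypes stays untested.

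Junctional zone trophoblast genes such as Psg21, Prl8a9 and Tpbpa were higher in the 13.5 day embryo of the maternal proximal duplication. The median of the junctional zone list lay 1.80 above the upper bound of random lists of equal brightness in that pair. That list holds Prl8a9 and Tpbpa and its position had been seen, so this is no separate test of a scaling shift. The median log2 ratio of the embryo arrays was -0.02 on 430A and -0.07 on 430B, too small for the ratios of these genes. Placental tissue in that embryo sample may be the source, since 91 placenta-enriched probe sets outside the trophoblast and decidua lists had a median log2 ratio of 0.27, at percentile 99.97 of random lists, with 15 at least 2-fold higher and 0 lower. Labyrinth trophoblast and decidua markers had medians of 0.05 and 0.16, so a source other than the junctional zone is less well seen. The higher Ahsg, Apoa1 and Comp in the same embryo are not covered by this, and a biological difference between the genotypes stays untested.

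Xist was at least 2-fold different in 8 pairs, and Y-linked genes moved at least 2-fold the other way in 7 of them and the same way in 0. The smallest size of the Xist log2 ratio over these pairs and the other scalings was 2.17. The scalings differ too little to bring such a ratio under 2-fold, so this is no separate test of scaling. On the arrays that gave these Xist ratios the median log2 ratio was at most 0.13 in size, on U74A in heart, too small for these ratios. The samples of 7 pairs may differ in the sex of the animals, which the labels do not give. In the placenta of the proximal comparison Xist had a log2 ratio of 2.22. No Y-linked gene that reached the array median went 2-fold the other way there, Eif2s3y being at 0.11 and Kdm5d at -0.41. A Kdm5d probe set below the array median, 105119_i_at, was at -1.69 or lower. No explanation was tested for the Xist ratio in this placenta.

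For Peg3 on U74A, 1 of 35 splits of the 8 arrays, the real one, called 2 probe sets, and the highest of the others called 1, with 3 splits that could not be fitted. Only 8 of the 35 part the arrays of every tissue as the real one does, the others leaving tissues unparted, and 8 are too few for a share under 0.05. The real split called 0 on U74B and on U74C, so that every split that could be fitted, 32 of 35 and 10 of 10, called as many whatever the data, and the counts say nothing about chance there. The highest other split called 1 on each.

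Genes far from their own values in other tissues were found in 5 of the 25 genes measured in 4 or more tissues. The criterion was that of Dixon, the gap to the nearest other value divided by the range. It flags about 1 in 20 by chance only where values are normal and of equal spread. The SD of the log2 ratios over genes was 0.498 in the embryo pair and 0.972 in the liver pair. That rate therefore does not hold here, and 5 of 25 cannot be read as more than chance. The log2 ratio of Ube3a was 2.79 in brain and between -0.44 and 0.31 in the other tissues, but the brain value came from 1416680_at, with 1431224_at at -0.48, 1445727_at at -0.25 and a median of all its probe sets of 0.78. Below the array median in brain, 1416681_at was at 1.02 or higher, 1416682_at at 1.09 or higher and 1425206_a_at at 0.54. Igf2 stood at 0.88 in liver, the pair with different scan days, and between -0.12 and 0.14 elsewhere. Kcnq1, a potassium channel gene, was at -0.81 in carcass and between 0.17 and 0.26 elsewhere. Osbpl5 was at 1.39 in placenta and between -0.13 and 0.30 elsewhere. Pdxdc1 was at 4.75 in placenta and at -4.54 or lower in carcass, heart and liver.

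Genes that moved at least 2-fold in opposite directions in different tissues numbered 8 of 40 examined, and the difference between tissues was not tested. Ampd3 was at 3.01 in placenta and -1.07 in heart. Inpp5f was at 1.18 in placenta and -3.43 in brain, on different array types. Kcnq1ot1, the antisense transcript of the distal cluster, was at 1.06 in embryo and -2.68 or lower in carcass, on different array types. Pdxdc1 was at 4.75 in placenta and -4.72 or lower in liver. In the distal comparison Atp10a was at 2.17 or higher in placenta and -1.71 in embryo. Xist was at 4.76 or higher in the distal embryo and -4.08 in the distal placenta, and Eif2s3y was at 2.74 or higher in that placenta and -2.68 or lower in that embryo, with Kdm5d at 2.22 or higher and -1.39.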

How the results depend on the processing

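The exclusion of chromosome X and Y genes, the exclusion of marker lists and the 8-fold size were chosen after the data had been seen. Peg3 on the older arrays passed under every setting run, and no direction reversed. Of 565 values of single genes under other settings, 453 kept their side of the threshold or stayed within the technical spread, 59 moved by more and 53 lost their call, 26 of these without tissue pairs. On the older set, leaving out 1 tissue in turn gave 2 to 4 calls, with 4 without liver and 4 without placenta. Over brain and embryo the 20 calls became 42 without further scaling, 15 higher and 27 lower, with all 20 among them, and 0 without pairs. In the distal test the 6 calls became 12 at the 75th percentile and 13 without further scaling, with all 6 among them, 3 without a filter, 2 without trend and 0 without pairs. More probe sets are tested without a filter, and the spread between tissues enters the error without pairs; the cause was not tested for the others. Leaving out a tissue was not run where 1 pair would be left.

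A 3-fold size counts fewer genes by construction, 393 in brain, 645 in carcass, 188 in embryo, 368 in heart, 1170 in liver, 901 in placenta, 946 in maternal and 1018 in paternal liver against normal, 918 in distal embryo and 507 in distal placenta. So does a filter at 2 array medians, with 658 in brain, 1024 in carcass, 235 in embryo, 446 in heart, 997 in placenta, 1192 in maternal liver against normal, 1003 in distal embryo and 571 in distal placenta. Floors cannot change the counts at 2-fold, and with these 20 fixed counts included, 72 of 90 stayed within 1.5 times the count reported.

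The share of genes on chromosomes 7 and 11 at 8-fold was 39.3% in brain, 66.7% in embryo, 23.8% in heart, 15.8% in liver, 26.9% in placenta, 13.1% in paternal liver against normal, 21.4% in distal embryo and 24.0% in distal placenta. At 3-fold it was 19.6% in brain and 16.0% in distal placenta, and at the higher filter 16.1% in heart. Fewer genes are behind these shares.

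The median of paternally expressed genes of proximal chromosome 7, with Peg3 and Ndn, was -3.09 in brain and -1.81 in placenta at a floor of 0.5, -4.58 in brain and -4.48 in embryo at 0.05, and -3.43 in brain with the median of a gene's probe sets. A floor bounds ratios of genes under it. Of 160 list medians 148 stayed within the technical spread. Signal under the floor, about 1 value in 5, limits the size of ratios such as that of Snhg14.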

Other observations

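The tests behind these values were chosen before the data were examined, but the genes named in the paragraph on Pdxdc1 and in that on the liver arrays, and Dlk1, Igf2r, Igf2os and Fos, were picked after their values were seen. Imprinted genes of other chromosomes moved little as a list in the proximal comparison, with medians of 0.03 in brain, 0.01 in carcass, -0.06 in embryo, 0.03 in heart, -0.22 in liver and 0.25 in placenta. Single members stood apart. Dlk1, a Notch ligand homologue expressed from the paternal copy, had a signal of 61.2 in the maternal, 34.3 in the normal and 11.4 in the paternal liver. Meg3, the maternally expressed RNA beside it, had log2 ratios of 1.83 in heart and 1.29 in placenta. The deiodinase gene Dio3 was at -1.95 in carcass, Peg10 at -1.72 in liver, Calcr at 1.05 in brain and the receptor gene Igf2r at 1.08 in embryo. In the distal comparison Airn was at -1.22 and Rasgrf1 at -2.17 in placenta.

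The paternally expressed genes of distal chromosome 7, which both genotypes of the proximal comparison carry from both parents, had a median of 0.91 in embryo, with Igf2os at 0.91, and of -0.12 in carcass. In embryo Kcnq1ot1 was at 1.06 and Igf2 at 0.09. The carcass values lay far apart, with Ins2 at 3.42 or higher (100150_f_at), Kcnq1ot1 at -2.68 or lower and Igf2 at -0.12. Another Ins2 probe set, 161849_r_at, was under the floor in both carcass arrays. Maternally expressed genes of the distal cluster had medians of -0.13 in brain, 0.04 in carcass, 0.07 in embryo, 0.18 in heart, 0.25 in liver and 0.12 in placenta in the proximal comparison. The cell cycle inhibitor gene Cdkn1c had signals of 64.9 and 31.6 in carcass, and in liver it was 1.75-fold higher in the maternal duplication than in normal.

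Some transcripts were near the floor in one sample and bright in another. Probe set 97713_at of Pdxdc1 had 9.14 in the maternal and 0.34 in the paternal placenta, but 0.073 and 5.83 in carcass, 0.134 and 6.46 in heart and 0.107 and 6.57 in liver. In the distal placenta it had 11.2 against 0.22 in normal. Gm9519 had 17.5 and 0.152 in the placenta of the proximal comparison, and 23.5 and 1.38 in the distal one. Xaf1 had 9.77 and 0.546 in placenta, but 2.08, 0.566 and 10.7 in maternal, normal and paternal liver. No explanation was tested for these.

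Genes of the stress response, of hypoxia and of the IGF axis also differed in single pairs. Igfbp6, a binding protein gene, was at 2.88 or higher in liver, 2.60 in placenta, 0.84 in carcass and -1.28 in heart, and Igfbp3 at 1.49 in brain. Of the stress genes, Fos was at -2.88 and Ddit3 at 2.90 in liver, a pair of arrays from different scan days, and the list had a median of -0.36 there. Adm, a vasodilator peptide gene, was at 1.95 in the placenta with the maternal proximal duplication, where hypoxia genes had a median of 0.27, and Car9 was at -0.72 there, 1.96 in carcass and 2.30 in liver. Glia markers had medians of -0.53 in carcass and 0.09 in the distal embryo. Bone and cartilage markers had a median of -1.18 in heart, and neuron markers 1.45 in the distal placenta, where Syt1 was at 1.61.

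In newborn liver, maternal and normal arrays shared day and scanner. G0s2, a lipolysis inhibitor gene, had 1.37 in the maternal, 13.2 in the normal and 1.14 in the paternal liver. Apol7a had 0.524, 11.8 and 23.5. Igf2 had 280.3, 351 and 153, and probe set 93028_at, which the platform annotation assigns to H19 and Mir675, had 388, 420.3 and 212.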
